A study of Homo sapiens with 6 samples.

How the data were processed

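The series holds 6 Illumina HT-12 expression arrays of H1993 cells, 2 for each of 3 labelled groups: control shRNA, BRMS1 shRNA, and BRMS1 with Twist1 shRNA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit, checked on a Bioanalyser and made into biotinylated cRNA.

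The values used were the deposited table of processed intensity values, 1 column per array, matched to the samples by its header. Per the submitters' processing notes, GenomeStudio was used, and its version, background method and normalization are not given in the sources used here. From the values, the scale is linear, with a median of 10.6 units on each array and a range from -27.1 to 35652; 27.8% to 27.9% of values per array were negative, which is what subtraction of a background leaves. The sorted values of the arrays differed by at most 0.632 units, as quantile normalization leaves them. A table of scanner signals was read but not used here, because its 24 data columns carry names that match no sample label. The design had been written for scanner signals with detection p-values; without them the deposited intensities were only log2-transformed, and the fallback filter of the design was used.

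Intensities were transformed to log2(value + 50). Fold changes are on this scale, which understates the change of dim genes. The background limit was set at 27.1 units, the size of the most negative value, and a group counted as within background when both of its arrays were at or below it. Where 1 group of a comparison was within background, the fold is given as a bound, the brighter group's geometric mean over that limit, and no fold is given where both were. Probes were named from the platform annotation paired with the value table: of 47322 probes, 30113 had 1 gene symbol, 8 had several and 17201 had none. Symbols were checked by gene identifier against the RefSeq gene table of GRCh38.p14, which matched 30074 probes and changed 0 symbols. The genome build behind the probes is not given in the sources used here, so no coordinates are printed. Probes with a mean log2 value above the median of all probes entered (23661). The brightest probe stood for each gene, and unnamed probes were kept as their own features, which gave 19112 features, of which 12793 were named genes. Where a gene had further probes, their signs were compared with that of the probe used.

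Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with all 6 arrays in 1 fit of 3 group means and no covariate, 3 residual degrees of freedom and 4.48 prior degrees of freedom. All adjusted p-values are Benjamini-Hochberg, over the features tested, and the threshold was 0.05. Errors of log2 changes are SE from limma, and errors of intensities are SD over 2 arrays. Across lists, limma's camera was run two-sided with a preset correlation of 0.01 between genes and again with an estimated correlation. The 22 lists were epithelial junctions and keratins, mesenchymal markers, EMT transcription factors, NF-kB target genes, the SIN3-HDAC complex, invasion proteases and inhibitors, integrins with laminins and matrix receptors, DNA replication and G1/S, mitosis and G2/M, p53 target genes, BCL2 family and caspases, interferon response, endoplasmic reticulum stress and amino acid response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta response, MET and MAPK pathway output, NRF2 target genes, lung epithelial lineage, and fibroblast, leukocyte and endothelial markers. The endothelial list had 1 measured member and was not tested as a list, leaving 21. Members of several lists overlap. Counts of list members are given with p-values adjusted over all features and, where they differ, adjusted over the list alone.

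The comparisons, the threshold, the lists, the probe rule, the fallback filter and the rule for named genes were fixed before the data were examined. That rule named BRMS1 and TWIST1, the 10 largest rises and falls per comparison among called genes whose groups did not overlap, up to 4 members of each list by adjusted p, a fixed set of EMT and NF-kB genes, and up to 10 genes with the largest opposite changes. Outside that rule, MTAP and GSTT1 come from tests whose rules were written before the values of these genes were seen. SPINT1, CDKN2A and the genes named in the last part of the closing section were named after their values were seen. So were HMOX1, MET, COL5A2 and ALDH3A1 in comparisons where the rule had not named them. The offset of 50, the background limit, the 300-unit cutoff for switches, 5 of the alternatives (offsets of 30 and 100, a floor at the background limit, and filters on the background limit and on the 75th percentile), and the summary of disjoint arrays as a share with the opposite sign were also chosen after the values were seen. Features of the Y chromosome and genes tied to sex were tested but left out of every table and count of named genes (20 features). Opposite changes in comparisons that share arrays were set beside 100 simulated data sets with unchanged groups and beside disjoint choices of arrays.

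The fit was tested before use on simulated data for BRMS1 knockdown against control, with 200 of 19112 features changed. There, 68.0% of changes of 1 on the log2 scale and 93.0% of changes of 2 were called, and 2 unchanged features were called. These rates hold for that few changed features, whereas 9143 were called in the data. Alternatives were tried for the filter, the offset, low values, the probe rule, the variance model, the samples in the fit, the threshold, the replicate number, the list correlation and leaving out each array. For arrays, precision is limited by their number; with 2 per group, leaving out 1 leaves a group with a lone array that is assumed to vary like the others.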

Results

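Gene expression was measured in H1993, an established human lung adenocarcinoma cell line, on 6 Illumina HT-12 bead arrays. The cells had received lentivirus encoding a control shRNA, an shRNA against BRMS1, or shRNAs against both BRMS1 and Twist1, with 2 arrays per group. BRMS1 is a metastasis suppressor that works in the SIN3-HDAC corepressor complex, and Twist1 is a transcription factor that drives epithelial-mesenchymal transition (EMT). Each array gave 47322 probe intensities, of which 36.5% exceeded the background limit of 27.1 units. The sources used here do not say that the arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and 2 arrays per group limit the precision. The median SD between the arrays of a group, on the log2 scale, was 0.083 for control, 0.090 for BRMS1 knockdown and 0.086 for the arrays labelled double knockdown.

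The targeted genes were read first, array by array. BRMS1 gave 236 and 278 units on the control arrays, 1.45 and 7.55 on the arrays labelled BRMS1 knockdown, and 258 and 233 on the arrays labelled double knockdown. The BRMS1 probe (ILMN_1719165) was thus within background only on the arrays labelled BRMS1 knockdown, and was at least 9.47-fold lower there than on control (log2 change -2.49 ± 0.12 SE, limma adjusted p = 2.1e-06). On the arrays labelled double knockdown, BRMS1 differed from control by -0.054 on the log2 scale (95% interval -0.33 to 0.22, limma adjusted p = 0.803), and was at least 9.06-fold higher than on the BRMS1 knockdown arrays (limma adjusted p = 2.6e-06). These 2 arrays therefore went against their label for BRMS1, and are called the arrays labelled double knockdown throughout. TWIST1 (probe ILMN_1672908) gave 134 and 173 units on control, 454 and 523 on BRMS1 knockdown, and 85.2 and 58.6 on the arrays labelled double knockdown. It was higher on the arrays labelled BRMS1 knockdown than on control, by 1.41 ± 0.15 (limma adjusted p = 1.7e-04). On the arrays labelled double knockdown it was lower than on BRMS1 knockdown, with a log2 difference of -2.15 ± 0.15 (limma adjusted p = 1.9e-05), and lower than on control, with -0.74 ± 0.15 (limma adjusted p = 0.015; 0.095 without control replicate 2 and 0.094 without replicate 2 of the arrays labelled double knockdown).

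**Figure D1:**
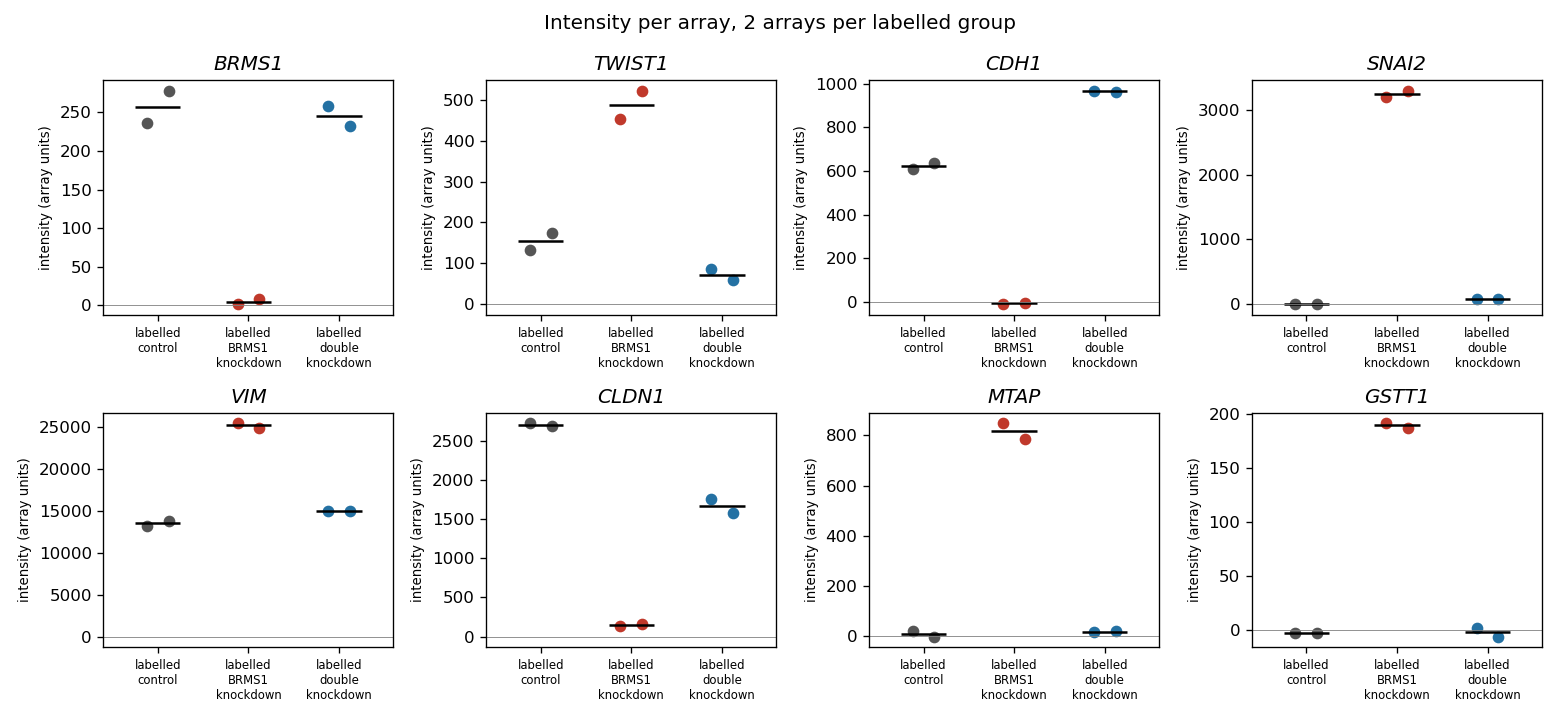
Intensity (array units) of 8 genes on each of the 6 arrays, with points for arrays and a bar for the mean of the 2 arrays of each labelled group. BRMS1 stood at 257 units on control, 4.50 on BRMS1 knockdown and 246 on the arrays labelled double knockdown, and MTAP and GSTT1 were above background only on the BRMS1 knockdown arrays.

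The arrays labelled BRMS1 knockdown stood apart from the other 4 arrays. Across all probes, which are not independent replicates, Pearson's r of log2 values was 0.989 to 0.991 within groups and 0.981 between control and the arrays labelled double knockdown. It was 0.929 to 0.931 between the BRMS1 knockdown arrays and any array of the other groups. This separation moved with every gene group described below that changed between the BRMS1 knockdown arrays and the others.

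The first comparison, BRMS1 knockdown against control, was made to ask whether loss of BRMS1 moves cells toward a mesenchymal state. Rose and fell here mean higher or lower on the arrays labelled BRMS1 knockdown. These arrays also stood apart in MTAP and GSTT1, so the differences cannot be ascribed to loss of BRMS1 alone. CDH1, which encodes E-cadherin, fell from 621 ± 19.8 units (SD, n = 2) to background, at least 22.9-fold, and the tight junction gene CLDN1 fell from 2705 ± 28.1 to 145 ± 15.3. SNAI2, an EMT transcription factor, rose from background to 3248 ± 73.7 units, at least 120-fold. VIM, which encodes the mesenchymal intermediate filament vimentin, rose from 13495 ± 429 to 25153 ± 375. Beside these, most NRF2 target and lung lineage transcripts were lower and most transcripts of the hypoxia and glycolysis list higher.

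Of 19112 genes and unnamed probes tested, 9143 changed at an adjusted p under 0.05 in limma, 4600 upward and 4543 downward. At least 2-fold changes were called for 2722, of which 1179 were higher and 1543 lower, and at least 8-fold changes for 304, of which 106 were higher and 198 lower. Both arrays of one group lay above both arrays of the other for 72.1% of features, where chance gives 33.3%. Among the 10 genes picked for large rises, 8 were within background on control, so their folds are bounds and their order is not known: the metallothionein MT1E (at least 588-fold), the interstitial collagenase MMP1 (349), the cytokine IL1A (176), RAC2 (158), IL1B (156), G0S2 (154), SNAI2 (120) and the collagen cross-linking enzyme LOX (113). The acute-phase gene SAA1 rose by 6.50 ± 0.12 and PRICKLE1 by 5.63 ± 0.13 on the log2 scale. Of the 10 picked for large falls, 9 were within background under BRMS1 knockdown: the adhesion gene CEACAM6 (at least 802-fold lower), the aldo-keto reductase AKR1B10 (680), the matrix protease MMP7 (434), the aldehyde dehydrogenase ALDH3A1 (400), CRIP1 (368), CXCL5 (334), the glutathione peroxidase GPX2 (325), AKR1B15 (296) and UCHL1 (230). S100A4 fell by 8.14 ± 0.14 on the log2 scale. CEACAM6 went from 21705 ± 904 units to background, and MT1E from background to 15913 ± 577. All 20 genes had to pass the test to be picked, and their limma adjusted p was at most 9.6e-08. In all, 186 named genes were within background on both arrays of one group and above 300 units on both arrays of the other, 60 of them off in control and 126 off under BRMS1 knockdown.

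Of 27 measured genes of epithelial junctions and keratins, 18 fell, 1 rose and 8 did not pass the test. The adhesion molecule EPCAM (-4.85 ± 0.12 on the log2 scale), plakoglobin (JUP, -3.90 ± 0.11) and CLDN1 (-3.82 ± 0.11) fell, as did CDH1, and the protease inhibitor SPINT1 rose by 0.41. The list as a whole shifted down with camera (adjusted p = 5.6e-06), a call lost with an estimated correlation (adjusted p = 0.264 with an estimated correlation). Of 23 mesenchymal markers, 14 rose and 3 fell, and adjusted over the list alone 15 rose and 3 fell. LOX, TAGLN (4.83 ± 0.11), THBS1 (2.42 ± 0.09) and the N-cadherin gene CDH2 (1.23 ± 0.10) rose, and FN1, which encodes fibronectin, rose from background to 132 ± 7.53 units. S100A4 was the member with the largest fall. The mesenchymal list shifted up (camera adjusted p = 0.0026; adjusted p = 0.170 with an estimated correlation). Of 12 EMT transcription factors 6 rose, among them SNAI2, TWIST1 and ZEB2 (at least 8.62-fold), and 3 fell, among them ID2 (-2.06 ± 0.10) and SOX4 (-2.10 ± 0.12). Adjusted over the list alone, 7 rose and 3 fell, and the list as a whole did not pass (camera adjusted p = 0.209). The brightest probes of OCLN, SNAI1 and ZEB1 were within background on all 6 arrays and were not tested.

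All 18 measured NRF2 target genes, which encode enzymes of redox and xenobiotic metabolism, changed: 17 fell and 1 rose. AKR1C2 (-4.93 ± 0.11), AKR1C3 (-4.93 ± 0.09) and the transporter gene ABCC2 (at least 28.7-fold) fell, whereas HMOX1, which encodes heme oxygenase, rose by 0.74 ± 0.10. The list shifted down (camera adjusted p = 4.9e-09; adjusted p = 0.119 with an estimated correlation). Of 12 lung epithelial lineage genes 9 fell and none rose; adjusted over the list alone 9 fell and 1 rose. AGR2 fell from 5231 ± 59.3 units to background, and the pioneer factors FOXA1 (-2.76 ± 0.10) and FOXA2 (-2.50 ± 0.09) fell (camera adjusted p = 2.4e-05 for the list; adjusted p = 0.119 with an estimated correlation). Of 25 hypoxia and glycolysis genes 21 rose and 2 fell. ANGPTL4 rose by 4.21 ± 0.09, the aldolase ALDOC by 2.93 ± 0.11, PFKFB4 by 2.12 ± 0.10 and the mitophagy receptor BNIP3L by 2.02 ± 0.12, and the list shifted up (camera adjusted p = 1.1e-07; adjusted p = 0.119 with an estimated correlation).

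Among 29 NF-kB target genes 14 rose and 10 fell. IL1A and IL1B rose as given above, IL6 rose by 2.15 ± 0.15, to 265 ± 18.2 units, and CXCL8 by 1.55 ± 0.11, while the chemokine CCL2 fell from 4303 ± 117 units to background and TNFAIP2 fell at least 11.1-fold. RELA, the p65 subunit, rose by 0.56 ± 0.10. NFKBIA, which encodes an NF-kB inhibitor, differed by 0.24 ± 0.13 (limma adjusted p = 0.168, and 0.0498 with a mean-variance trend and robust eBayes). BCL2A1 differed by -0.31 ± 0.15 (limma adjusted p = 0.130), and by -0.53 without control replicate 1. The list did not shift as a whole (camera adjusted p = 0.562). In the SIN3-HDAC complex, of which BRMS1 is a member, 7 of 17 genes rose and 7 fell, among them SAP130 (1.17 ± 0.10), SAP18 (0.96 ± 0.12) and RBBP7 (-1.25 ± 0.10), with a camera adjusted p of 0.972 for the list.

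The remaining lists did not pass camera. Invasion proteases and inhibitors had 9 higher and 9 lower of 20, with MMP1 and ADAMTS1 (at least 89.2-fold) up and MMP7 and SPP1 (at least 110-fold) down. Integrins, laminins and matrix receptors had 5 higher and 8 lower of 19 (6 and 8 adjusted over the list alone), with LAMB3 up by 2.78 ± 0.10 and ITGB4 at least 5.49-fold lower. DNA replication and G1/S genes had 2 higher and 9 lower of 24 (2 and 10 adjusted over the list alone; camera adjusted p = 0.070), and mitosis and G2/M genes 13 higher and 7 lower of 28. For p53 target genes the counts were 4 higher and 7 lower of 18 (4 and 8 adjusted over the list alone), with GADD45A up by 2.17 ± 0.10. BCL2 family and caspase genes gave 8 higher and 7 lower of 25, and interferon response genes 7 higher and 7 lower of 26 (1 of them within background in both groups), with IFITM3 up by 4.94 ± 0.15 and OAS3 at -1.49 ± 0.10. Endoplasmic reticulum stress and amino acid response genes gave 10 higher and 8 lower of 25 (11 and 8 adjusted over the list alone), and cholesterol synthesis genes 4 higher and 6 lower of 19. TGF-beta response genes gave 7 higher and 5 lower of 17, with CCN1 up by 3.74 ± 0.11 and BAMBI at -3.98 ± 0.11. MET and MAPK pathway output genes gave 12 higher and 7 lower of 23, and MET itself, a receptor tyrosine kinase, fell by 1.05 ± 0.10. Of the markers of other cell types, 3 of 7 fibroblast markers rose and none fell, namely PDPN (at least 11.1-fold), THY1 (1.29 ± 0.11) and FAP. Of 7 leukocyte markers, 2 rose and 1 fell (none and 1 without replicate 1 of either group), and the single measured endothelial marker, PECAM1, rose at least 4.75-fold. Lists with no second count had the same counts adjusted over the list alone. The median, mean and camera direction differed in sign for the SIN3-HDAC complex, integrins, BCL2 family and leukocyte lists. The BRMS1 knockdown arrays also differed from the other 4 arrays in MTAP, at 818 ± 43.7 units against 8.15 ± 15.1 on control, and in GSTT1, at 190 ± 3.03 against -2.48 ± 0.28, so the changes above are differences between these labelled arrays. Of 2167 called genes with further probes, 300 had a probe of the other sign, 10 of them by at least 2-fold.

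**Figure D2:**
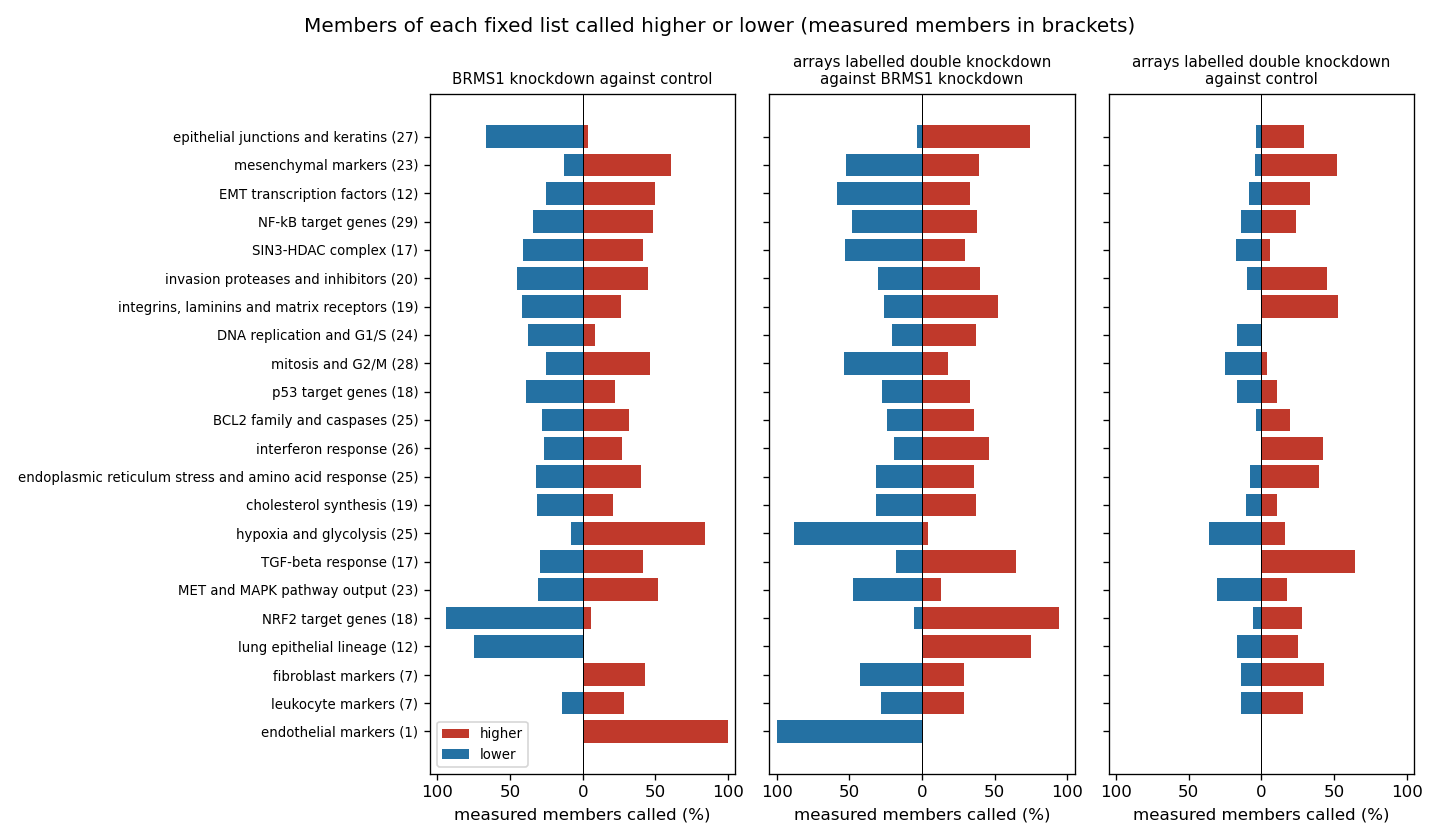
Percent of the measured members of each of the 22 gene lists called higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in limma, for the 3 comparisons of labelled groups, with the number of measured members in brackets. NRF2 target genes had 17 of 18 members lower under BRMS1 knockdown and 17 of 18 higher in the arrays labelled double knockdown against BRMS1 knockdown.

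The second comparison, the arrays labelled double knockdown against BRMS1 knockdown, was made to ask what the added Twist1 shRNA does in BRMS1-depleted cells. It cannot answer this, because BRMS1 was at control level on the arrays labelled double knockdown. Both BRMS1 and TWIST1 differed between the groups compared. On the arrays labelled double knockdown, CDH1 was 964 ± 4.38 units against background under BRMS1 knockdown, at least 35.6-fold higher, and CLDN1 was higher by 3.14 ± 0.11. SNAI2 was lower by a log2 difference of -4.71 ± 0.12, at 76.5 ± 7.12 units, ZEB2 was within background, and VIM differed by -0.75 ± 0.09. CDH2, by contrast, was higher still, at 5417 ± 371 units against 3309.

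In limma, 9402 of 19112 features differed at an adjusted p under 0.05, 4630 higher and 4772 lower on the arrays labelled double knockdown. At least 2-fold differences were called for 2688, of which 1549 were higher and 1139 lower, and at least 8-fold differences for 285, of which 193 were higher and 92 lower. Groups did not overlap for 72.4% of features, where chance gives 33.3%. Of the 10 genes picked for large positive differences, 9 were within background under BRMS1 knockdown and have bounds: AKR1B10 (at least 984-fold higher), CEACAM6 (807), ALDH3A1 (705), AKR1B15 (539), the secreted phosphoprotein SPP1 (476), CXCL5 (461), UCHL1 (352), CRIP1 (346) and MMP7 (310). S100A4 was higher by 7.74 ± 0.14 on the log2 scale. On the negative side, MMP1 (at least 349-fold lower), RAC2 (158), G0S2 (154), LOX (113), SAA2 (94.5) and the cyclin gene CCND2 (63.7) were within background on the arrays labelled double knockdown. CCND2 had a log2 difference of -5.60 with all arrays, -3.09 without BRMS1 knockdown replicate 1 and -2.81 without replicate 2. For 1 probe the last 2 values would lie on either side of the first. Another CCND2 probe, with a smaller difference, was therefore the brightest in at least 1 of these fits. The measurable log2 differences were those of MT1E (-7.05 ± 0.12), SAA1 (-6.10 ± 0.12), IL1A (-5.45 ± 0.11) and PRICKLE1 (-5.08 ± 0.13). In this comparison 154 named genes switched between background and over 300 units.

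Of 27 epithelial junction and keratin genes 20 were higher and 1 lower (20 and 2 adjusted over the list alone), among them EPCAM (5.03 ± 0.12) and KRT19 (at least 75.1-fold), with a camera adjusted p of 1.0e-08 and an adjusted p = 0.198 with an estimated correlation. NRF2 target genes had 17 higher and 1 lower of 18, with AKR1C2 at 4.79 ± 0.11 and HMOX1 at -2.59 ± 0.10 (camera adjusted p = 1.3e-09; adjusted p = 0.104 with an estimated correlation). Lung epithelial lineage genes had 9 higher and none lower of 12 (9 and 1 adjusted over the list alone), with AGR2 at least 159-fold higher and FOXA2 at 3.57 ± 0.09 (camera adjusted p = 9.6e-05; adjusted p = 0.142 with an estimated correlation). Of 25 hypoxia and glycolysis genes 22 were lower and 1 higher, with ANGPTL4 at -4.94 ± 0.09 and ALDOC at -3.01 ± 0.11 (camera adjusted p = 1.0e-08; adjusted p = 0.104 with an estimated correlation).

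Mesenchymal markers split, with 9 higher and 12 lower of 23 (10 and 12 adjusted over the list alone; camera adjusted p = 0.657): LOX and TAGLN (-4.09 ± 0.11) were lower, and S100A4, COL5A2 (3.68 ± 0.12) and CDH2 (0.70 ± 0.10) higher. EMT transcription factors had 4 higher and 7 lower of 12, and NF-kB target genes 11 higher and 14 lower of 29 (12 and 14 adjusted over the list alone). CCL2 was at least 180-fold higher and IL1B lower, at -4.88 ± 0.10, while IL6 differed by -0.01 ± 0.15 (limma adjusted p = 0.967). NFKBIA was lower, at -0.76 ± 0.13. RELA, at -0.32 ± 0.10, no longer passed with no filter on dim probes or without BRMS1 knockdown replicate 1 or 2 or either array labelled double knockdown (limma adjusted p of 0.097, 0.053, 0.119, 0.099 and 0.089). The SIN3-HDAC complex had 5 higher and 9 lower of 17, and invasion proteases and inhibitors 8 higher and 6 lower of 20 (9 and 6 adjusted over the list alone). Integrins and laminins had 10 higher and 5 lower of 19, with ITGB4 at least 20.9-fold higher. Replication and G1/S genes had 9 higher and 5 lower of 24 (9 and 7 adjusted over the list alone), and mitosis genes 5 higher and 15 lower of 28 (5 and 16 adjusted over the list alone; camera adjusted p = 0.055), with AURKA at -1.10 ± 0.10. TGF-beta response genes had 11 higher and 3 lower of 17, with PMEPA1 at 1.81 ± 0.11, and MET and MAPK output genes 3 higher and 11 lower of 23, with EGR1 at -2.33 ± 0.09 and MET at 1.35 ± 0.10 (camera adjusted p = 0.055 for each). Interferon response genes had 12 higher and 5 lower of 26 (camera adjusted p = 0.078), with HERC5 at 2.26 ± 0.09. The counts were 6 higher and 5 lower of 18 for p53 target genes, 9 and 6 of 25 for the BCL2 family and caspases, and 9 and 8 of 25 for endoplasmic reticulum stress. Cholesterol synthesis had 7 and 6 of 19 (8 and 6 adjusted over the list alone). Fibroblast markers had 2 higher and 3 lower of 7 (3 and 3 adjusted over the list alone), with LUM at least 8.56-fold higher, leukocyte markers had 2 and 2 of 7 (1 and 1 without BRMS1 knockdown replicate 1), and PECAM1 was at least 4.75-fold lower. Other lists had equal counts adjusted over the list alone. The median, mean and camera direction differed in sign for the SIN3-HDAC, replication, p53, leukocyte and fibroblast lists. MTAP and GSTT1 were within background on the arrays labelled double knockdown, at 18.0 ± 0.62 and -2.12 ± 5.56 units. Of 2234 called genes with further probes, 321 had a probe of the other sign, 9 of them by at least 2-fold.

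The third comparison, the arrays labelled double knockdown against control, gives the net difference of the combined shRNAs; since BRMS1 did not differ, its direction cannot be ascribed to lower BRMS1 transcript. CLDN1 was lower, at -0.68 ± 0.11, and CDH1 higher, at 0.60 ± 0.11. The CDH1 call was lost without control replicate 1 or 2, without either array labelled double knockdown and with an offset of 30 (limma adjusted p of 0.074, 0.059, 0.067, 0.067 and 0.063). CDH2 (1.93 ± 0.10), CDH11 (at least 5.30-fold) and the collagen genes COL5A1 (2.64 ± 0.10) and COL5A2 (0.83 ± 0.12) were higher, SNAI2 rose from background to 76.5 ± 7.12 units, and VIM differed by 0.15 ± 0.09 (limma adjusted p = 0.321). The cytokine genes IL6 (2.14 ± 0.15) and CXCL8 (0.70 ± 0.11) rose.

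In limma, 3392 features differed, 1745 higher and 1647 lower. At least 2-fold differences were called for 432 of them, 273 higher and 159 lower, and at least 8-fold differences for 17, with 8 higher and 9 lower. Groups did not overlap for 59.5% of features. Picked for large rises were the tetraspanin TSPAN8 (5.56 ± 0.11, from 43.6 ± 2.62 to 4376 ± 351 units), IGFBP7 (3.76 ± 0.12), ANXA10 (3.36 ± 0.14), EFEMP1 (3.28 ± 0.12), NAMPT (2.92 ± 0.14) and COL5A1. SPINK6 (at least 27.2-fold), TSPAN7 (16.7), the transcription factor gene MECOM (12.3) and MPZL2 (12.3) rose from background on control. Picked for large falls were the secretogranin gene SCG2 (-3.90 ± 0.10), the fibrinogen chains FGB (-3.82 ± 0.13), FGG (-3.65 ± 0.12) and FGA (-2.74 ± 0.13), FXYD2 (-3.57 ± 0.11), HLA-DMB (-3.11 ± 0.12) and the glucose transporter gene SLC2A3 (-2.75 ± 0.12). The neuropeptide gene NTS fell from 3962 ± 94.9 units to background, at least 146-fold, as did NMUR2 (at least 19.2-fold), and FAM133A fell from 297 units to background. Between background and over 300 units, 5 named genes switched: SPINK6, MECOM and TSPAN7 were on, and NTS and NMUR2 off, on the arrays labelled double knockdown.

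TGF-beta response genes had 11 higher and none lower of 17 (13 and 0 adjusted over the list alone), led by PMEPA1 (1.63 ± 0.11), the transglutaminase TGM2 (1.59 ± 0.10) and SMAD7 (1.15 ± 0.11). SMAD7 was 0.57 without BRMS1 knockdown replicate 1, an array that does not enter this comparison. Another SMAD7 probe was thus the brightest in that fit and gave a smaller difference. Without replicate 2 of the arrays labelled double knockdown SMAD7 was 0.67 and not called, and the probe may differ there too. The list shifted up (camera adjusted p = 2.0e-08; adjusted p = 0.134 with an estimated correlation). Of 19 integrin, laminin and matrix receptor genes 10 rose and none fell (13 and 1 adjusted over the list alone), among them ITGB4 (1.63 ± 0.14), ITGA2 (1.28 ± 0.13) and LAMA5 (1.11 ± 0.13), with a camera adjusted p of 2.8e-06 and an adjusted p = 0.116 with an estimated correlation. Of 26 interferon response genes 11 rose and none fell (12 and 0 adjusted over the list alone), among them IFI44 (1.57 ± 0.13), HERC5 (1.13 ± 0.09) and IFI6 (1.01 ± 0.10; camera adjusted p = 1.5e-05; adjusted p = 0.116 with an estimated correlation). Mesenchymal markers had 12 higher and 1 lower of 23 (14 and 2 adjusted over the list alone), with FSTL1 at 2.52 ± 0.14 (camera adjusted p = 1.5e-05; adjusted p = 0.116 with an estimated correlation). Epithelial genes also had 8 higher and 1 lower of 27 (9 and 2 adjusted over the list alone), with MAL2 (at least 4.48-fold) and OVOL2 (2.03 ± 0.10) higher and CLDN1 lower (camera adjusted p = 0.011; adjusted p = 0.328 with an estimated correlation). The epithelial list no longer passed camera with no filter on dim probes (adjusted p = 0.056), with a filter at the 75th percentile (0.083) or without replicate 2 of the arrays labelled double knockdown (0.107). Without any 1 of the 4 arrays compared, 2 to 5 epithelial genes were called; for integrin and laminin genes it was 5, 4 and 4 without control replicate 1 or 2 or replicate 2 of the arrays labelled double knockdown, and for TGF-beta and interferon genes 7 each without that last array.

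Endoplasmic reticulum stress and amino acid response genes had 10 higher and 2 lower of 25 (12 and 3 adjusted over the list alone), with the serine synthesis enzyme PHGDH at 1.51 ± 0.10 and ATF3 at -1.07 ± 0.14 (camera adjusted p = 0.0070; adjusted p = 0.134 with an estimated correlation). Invasion proteases and inhibitors had 9 higher and 2 lower of 20, with SPP1 at 2.09 ± 0.15 and MMP10 at least 2.91-fold lower (camera adjusted p = 0.029; adjusted p = 0.190 with an estimated correlation). The protease list no longer passed camera with low values set to the background limit (adjusted p = 0.118), with a filter on that limit (0.052) or without replicate 2 of the arrays labelled double knockdown (0.055). DNA replication and G1/S genes had 4 lower and none higher of 24 (10 and 0 adjusted over the list alone), the lower ones being POLE2, POLA1 (-0.58 ± 0.11), GINS2 (-0.47 ± 0.12) and RRM2 (-0.35 ± 0.10) (camera adjusted p = 1.1e-04; adjusted p = 0.134 with an estimated correlation). POLA1, GINS2 and RRM2 lost their calls without control replicate 1 (limma adjusted p of 0.055, 0.129 and 0.203), control replicate 2 (0.074, 0.140 and 0.109) and replicate 1 (0.070, 0.172 and 0.164) or 2 (0.057, 0.070 and 0.140) of the arrays labelled double knockdown. GINS2 and RRM2 also lost theirs with no filter on dim probes (0.102 and 0.160), the replicate number as a block (0.058 and 0.068) or an offset of 30 (0.064 and 0.065), GINS2 with low values set to the background limit (0.051), and RRM2 with only the 2 groups compared (0.059) or without BRMS1 knockdown replicate 1 (0.059) or 2 (0.059). Mitosis and G2/M genes had 7 lower and 1 higher of 28 (8 and 1 adjusted over the list alone), with AURKA at -0.65 ± 0.10 and MAD2L1 at -0.60 ± 0.09 (camera adjusted p = 0.0035; adjusted p = 0.134 with an estimated correlation). Without any 1 of the 4 arrays compared, the members called were 3 to 5 for endoplasmic reticulum stress, 5 to 7 for proteases, 1 for replication and 2 to 3 for mitosis.

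The other lists did not pass. EMT transcription factors had 4 higher and 1 lower of 12, the lower one being TWIST1, and ZEB2 was within background in both groups. NF-kB target genes had 7 higher and 4 lower of 29 (9 and 7 adjusted over the list alone), with CCL20 at -2.31 ± 0.11 and LTB at -2.17 ± 0.26. The SIN3-HDAC complex had 1 higher and 3 lower of 17, p53 target genes 2 and 3 of 18 (3 and 4 adjusted over the list alone), and the BCL2 family and caspases 5 and 1 of 25 (8 and 2 adjusted over the list alone). Cholesterol synthesis had 2 higher and 2 lower of 19. Hypoxia and glycolysis genes had 4 higher and 9 lower of 25, with SLC2A1 at 1.01 ± 0.10 and ADM at -1.33 ± 0.12. MET and MAPK output genes had 4 higher and 7 lower of 23 (6 and 9 adjusted over the list alone), with EGR1 at -1.06 ± 0.09. NRF2 target genes had 5 higher and 1 lower of 18 (8 and 1 adjusted over the list alone), the lower one being HMOX1 (-1.85 ± 0.10), and lung lineage genes 3 higher and 2 lower of 12, with FOXA2 at 1.07 ± 0.09 and FOXA1 at -1.37 ± 0.10. Fibroblast markers had 3 higher and 1 lower of 7 (4 and 1 adjusted over the list alone), with LUM at least 8.56-fold higher; FAP, counted as higher, was within background in both groups, and 1 higher and none lower were called with low values set to the background limit. In the last lists, leukocyte markers had 2 higher and 1 lower of 7, with CD14 at -2.42 ± 0.10, and PECAM1 was within background in both groups. Lists without a further count kept their counts adjusted over the list alone. The median, mean and camera direction differed in sign for the NF-kB, lung lineage and leukocyte lists. Without any 1 of the 4 arrays compared, no SIN3-HDAC gene was called, nor with no filter on dim probes; the members called were 2 to 3 for EMT transcription factors, 2 for p53, none to 2 for the BCL2 family, 4 to 6 for hypoxia, 4 to 5 for MET and MAPK, 2 to 3 for NRF2 and 2 for fibroblast markers. NF-kB had 7 without control replicate 2, and cholesterol synthesis 1 without control replicate 1, 2 without control replicate 2 and 1 without replicate 1 of the arrays labelled double knockdown. The count of 3392 fell to 1421 without control replicate 1, 1430 without control replicate 2, and 1492 and 1488 without replicate 1 or 2 of the arrays labelled double knockdown. TWIST1 no longer passed without control replicate 2 (limma adjusted p = 0.095) or replicate 2 of the arrays labelled double knockdown (limma adjusted p = 0.094), and its adjusted p ranged from 8.8e-04 to 0.095 over its alternatives.

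The last comparison asks how many genes called in BRMS1 knockdown against control differed the other way in the second comparison. The reservation again is that BRMS1 was at control level on the arrays labelled double knockdown. MT1E, MMP1, IL1A, LOX and SNAI2 were far higher on the BRMS1 knockdown arrays than in both other groups, and CEACAM6, AKR1B10, ALDH3A1, S100A4 and CDH1 far lower. In all, 7137 features were called in opposite directions, 3629 of them higher and 3508 lower under BRMS1 knockdown, and 84 were higher and 41 lower in both. Independent lists of these sizes would share 2249 in opposite directions, and simulated unchanged groups gave a mean of 0.04. With no group changed hardly any feature is called in either comparison, so the 0.04 is no yardstick for 7137. Opposite calls covered 78.1% of the 9143 features called between the arrays labelled BRMS1 knockdown and control. Both comparisons use the BRMS1 knockdown arrays with opposite sign. A real difference of those arrays from both other groups thus gives opposite calls by itself, which independent lists leave out. The correlation of log2 changes across features was -0.905, against -0.499 in the simulation, and the covariance was -0.72, against -0.0088. Disjoint arrays were averaged over 4 choices. Of genes picked for an at least 2-fold change, 97.9% had the opposite sign on the arrays not used to pick them. There the second difference was, at the median, 91.5% of the difference from control, with opposite sign. Both of these differences use the same BRMS1 knockdown array, so this share is not a disjoint value. Neither value carries a test.

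Against control, 6757 of the 9143 features were not called on the arrays labelled double knockdown, 1648 were called in the same direction as under BRMS1 knockdown and 738 in the other. Genes that kept a difference from control in the same direction included CDH2, IL6, FSTL1, EFEMP1 and MECOM, all higher, and NTS, NMUR2, HLA-DMB and SLC2A3, all lower. ALDH3A1 was among those that went beyond control, with a log2 difference from control of 0.82 ± 0.11.

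**Figure D3:**
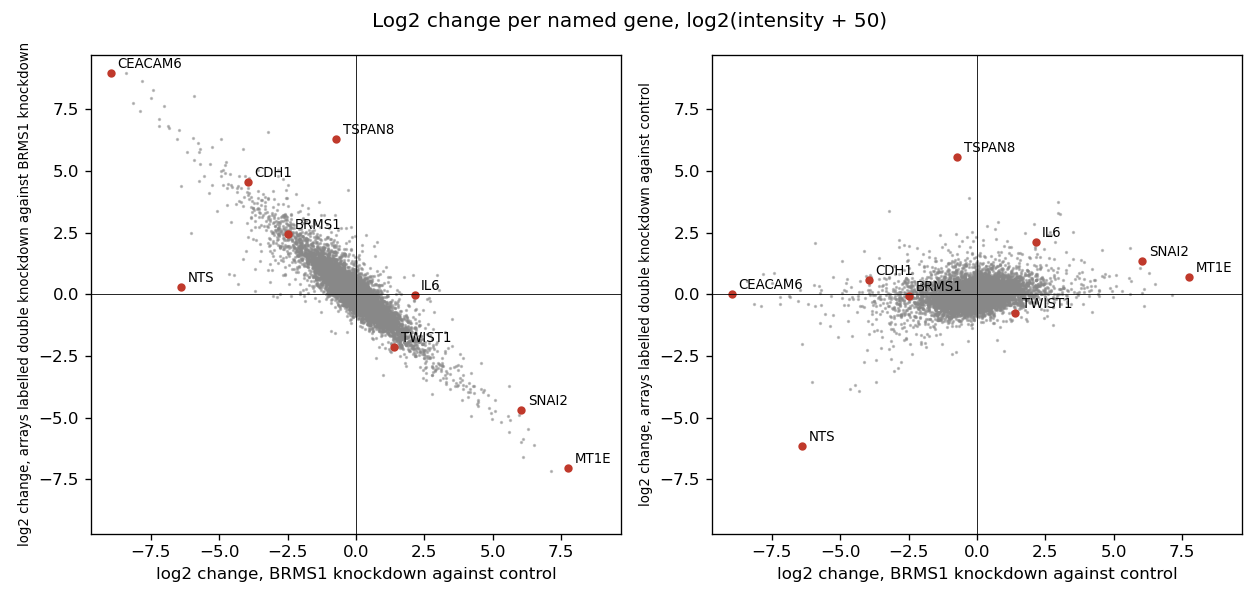
Log2 change of each named gene on the log2(intensity + 50) scale, with BRMS1 knockdown against control on the x axis and, on the y axis, the arrays labelled double knockdown against BRMS1 knockdown (left) or against control (right); points are genes and 9 are labelled. Most genes lie along the descending diagonal on the left, CEACAM6 at -8.96 and 8.97 and MT1E at 7.77 and -7.05, positions that depend on the offset where 1 group is within background, while NTS, TSPAN8 and IL6 lie off it.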

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

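Tests of chromosomal neighbours, of whether any of 12 genes that are often missing or silent in a genome switched, and of MTAP were written down before their results were seen; all other tests in this part, Fisher's exact test included, were chosen after the result was seen. The MTAP rule was written after the results of the other 2 had been seen. The brightness minimum of the neighbour test was changed after a first run, which had used 8824 genes in place of 7831 and gave ratios of 2.35, 2.21 and 1.81 in the order printed below.

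The BRMS1 effect against control differed between the shRNA sets: the tested difference between the arrays labelled double knockdown and those labelled BRMS1 knockdown was 2.44 on the log2 scale (95% interval 2.17 to 2.71). BRMS1-depleted cells on the arrays labelled double knockdown are argued against by this value and by the difference from control of -0.054 (95% interval -0.33 to 0.22). A signal too near background to read is argued against as well, since the mean of 246 units was 9.07 times the background limit. What stays open is that these arrays may hold cells with Twist1 knockdown and unreduced BRMS1, since TWIST1 was lower than on control by a log2 difference of -0.74 (95% interval -1.09 to -0.39), a call lost without control replicate 2 (limma adjusted p = 0.095) or replicate 2 of the arrays labelled double knockdown (0.094). A loss of BRMS1 protein without loss of transcript was not tested.

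The arrays labelled BRMS1 knockdown stood apart from the other 4, and a candidate explanation is RNA of another genome, or of a strongly diverged subline, on them. Log2 changes ran in chromosomal blocks, read from medians over 303 windows of 25 neighbouring genes. Their SD was 2.48 times that under shuffled gene order for BRMS1 knockdown against control and 2.34 times in the second comparison. It was 1.81 times for the arrays labelled double knockdown against control, and shuffled orders reached at most 1.15. Since the 1.81 exceeds this too, blocks alone do not single out the BRMS1 knockdown arrays. Co-regulated neighbours add to such ratios as well. MTAP was 818 units on the BRMS1 knockdown arrays and within background on the other 4. A deletion of the CDKN2A and MTAP neighbourhood in the cells of those 4 would leave it so. CDKN2A probe ILMN_1717714 gave 214 units on BRMS1 knockdown, 3.39 on control and 7.47 on the arrays labelled double knockdown. Probe ILMN_1744295 gave 104, -11.4 and -13.1 in the same order, whereas ILMN_1757255 was within background in every group. Of 12 genes that are often missing or silent in a genome, 4 were detected and 2 of these, GSTT1 among them, switched between control and BRMS1 knockdown, with the arrays labelled double knockdown as control, while 489 of 8605 other detected genes (5.68%) switched (one-sided Fisher's exact p = 0.018). Regulation by BRMS1 knockdown alone cannot be told apart from this, because expression does not separate a deleted gene from a silent one and the detected genes were few; no profile of another cell line was tested.

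Many genes differed one way in BRMS1 knockdown against control and the other way in the second comparison. Independent noise of the shared arrays is argued against as the whole cause by the covariance of -0.72, against -0.0088 in simulated unchanged groups. The simulation cannot exclude a real difference of the BRMS1 knockdown arrays, which would enter both comparisons with opposite sign. An undoing by Twist1 knockdown in BRMS1-depleted cells is argued against for these arrays by the BRMS1 difference from control of -0.054, whose interval lies above -1.25, the log2 value of a BRMS1 drop reduced by 50%. The pattern can also be put as the BRMS1 knockdown arrays standing apart from both other groups. Pearson's r was 0.929 to 0.931 with them, against 0.981 between control and the arrays labelled double knockdown. This restates the pattern and was not tested separately, and the effect of BRMS1 loss itself stays open.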

How the results depend on the processing

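Chosen after the values were seen were offsets of 30 and 100, a floor at the background limit, and filters on that limit and on the 75th percentile. Disjoint arrays gave a share of opposite signs of 97.9% over genes picked for an at least 2-fold change, and a shared array 98.6% over the same genes, summaries also chosen after the values were seen; over all called features the share with shared arrays was 94.6%. BRMS1 under BRMS1 knockdown and TWIST1 in the second comparison kept their direction and their side of the threshold under every alternative run, and no value of a named gene turned its sign while called: of 5114 values of 323 gene results, 4935 kept their side, 175 lost the call and 4 gained it, 151 of the losses being in the arrays labelled double knockdown against control. Leaving out 1 array gave 7411 to 8809 changed features for BRMS1 knockdown against control, 7679 to 9052 for the second comparison, 1421 to 3349 for the third, 6054 to 6254 opposite calls, 5 lists, 4 lists and 7 to 10 lists, -2.59 to -2.40 for BRMS1 and -2.31 to -1.99 for TWIST1. For the third comparison the counts were 1421 and 1430 without control replicate 1 or 2, and 1492 and 1488 without replicate 1 or 2 of the arrays labelled double knockdown, where fewer arrays were tested. In each of the 3 comparisons the upper end of the range of changed features came from leaving out an array outside that comparison. The ranges thus look narrower or higher than for the arrays compared. A minimum change of 1.5-fold gave 5758, 5808 and 1607 changed features in the 3 comparisons, and an adjusted p under 0.01 gave 1399 in the third, by construction of a stricter threshold. With no filter on dim probes the third comparison had 1805 changed features, and 8 lists passed in each of the first and second and 8 in the third; an offset of 100 gave 7 lists in the second; the cause was not tested. In the third comparison the called members of 12 of 22 lists fell by over 1.5 times with no filter on dim probes, of 6 with an offset of 30 and of 4 with the replicate number as a block. They rose so in 3 lists with an offset of 100, in 3 with a mean-variance trend and robust eBayes, and in 2 with the filter on the background limit. The filter at the 75th percentile lowered them so in 3 lists of the first comparison and 4 of the second. In the third it moved 5 lists, 2 of them downward. In the third comparison the epithelial list was lost with no filter and at the 75th percentile, the protease list with low values floored and the filter on the background limit, and both without replicate 2 of the arrays labelled double knockdown. With an estimated correlation 0, 0 and 0 lists passed camera, and 4, 4 and 7 had an unadjusted p under 0.05. The estimate was below the preset 0.01 for lists such as NRF2 (-0.057), lung lineage (-0.016) and mesenchymal markers (-0.020). For these, a higher correlation between genes is argued against as the reason. It was above 0.01 for the epithelial (0.103), TGF-beta (0.182), replication (0.032) and hypoxia (0.014) lists. With an estimated correlation, camera takes its p-values from a t distribution with only the 3 residual degrees of freedom of the fit. A preset correlation gives it far more. The NRF2 list went from a camera p of 2.3e-10 to 0.0063 despite its negative estimate. How much of each loss came from this was not tested. Same-numbered arrays did not deviate together (r of 0.0048, -0.0094 and -0.013 across features), so the numbers do not pair the arrays; with the replicate number as a block the counts were 8910, 9177 and 2856, the lists 5, 4 and 9, and the opposite calls 6933. Not run were no background correction, median scaling, another offset after normexp, a detection p filter and the slide as a block, which need scanner signals mapped to samples; the authors' processed values became the values used. Signal over background limits dim genes: 36.5% of probes per array exceeded the background limit.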

Other observations

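All comparisons in this part were chosen after the values were seen. Some genes differed from control in the same direction on both sets of shRNA arrays. NIBAN1 was 36.4 units on control, 502 under BRMS1 knockdown and 453 on the arrays labelled double knockdown, a rise of 2.68 ± 0.09 and 2.54 ± 0.09 on the log2 scale. The DNA sensor IFI16 went from 47.0 units to 539 and 466, and the inflammatory caspase gene CASP4 from 163 to 888 and 752. APOE, which encodes apolipoprotein E, was 228 units on control and within background in both other groups, at least 8.43-fold lower in each, and CTH, an enzyme of cysteine synthesis, went from 352 units to 56.7 and 51.4. NTS and NMUR2, a neuropeptide and a neuromedin receptor gene, were within background on all 4 arrays of the other groups.

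In all, 1648 features were called in the same direction in both comparisons against control, 757 higher and 891 lower, where independent lists of these sizes would share 420 and 391. The comparisons share the control arrays. Simulated unchanged groups gave 0.03 such features on average. With no group changed hardly any feature is called there, so the 0.03 is no yardstick for 1648. The covariance of log2 changes across features was 0.088, against 0.0088 in the simulation. The correlation was 0.253, against 0.501 in the simulation. The simulation holds only independent noise per array, so it cannot exclude a deviation common to both control arrays.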
